A study of Mus musculus with 15 samples.

How the data were processed

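Total RNA from frozen left ventricle was extracted with Tri Reagent and made into 3′-end libraries with the MERCURIUS BRB-seq kit, per the labels' protocols. The 15 libraries formed 3 groups of 5, sham saline, TAC saline and TAC NRG1, and the labels put all of them in batch 1. Reads were assigned to genes on genome build GRCm39, per the submitters' processing notes, and the aligner and read counter are not given in the sources used here. The deposited log2 values are the authors' log2 of reads plus 0.5, multiplied by a factor per library, as read from the spacing of the deposited values. Each file held 15258 genes.

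The whole reads behind the deposited log2 values were recovered by undoing that factor. Between 98.9% and 99.5% of values per library fell within 0.05 of a whole read, and 100.0% of those under 1000 reads did. Library totals were 2.02 to 5.62 M reads, with 13738 to 14762 genes holding a read in each library. Printed CPM are the deposited values taken out of the log and divided by 1000, so they carry the authors' scaling. No libraries of a group were duplicates, as the chi-square per degree of freedom between them was 2.27 to 12.1 (5 libraries per group).

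The analysis plan, fixed before the data were examined, assumed raw counts and a test made for counts. The files held scaled log2 values, so limma 3.58.1 in R 4.3.3, with a trend of spread on mean level, was fitted to the deposited log2 values of all 15 libraries. Genes needed 2.95 reads per M (10 in the median library) in at least 5 libraries and 15 reads in total, which kept 11018 genes and left out 4240. The comparisons were TAC saline against sham saline, TAC NRG1 against TAC saline and TAC NRG1 against sham saline, each two-sided with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The median standard error of a log2 fold change was 0.16. "Rose" and "fell" are used for genes past the threshold.

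Of 40 gene lists fixed in the plan, 37 had 3 or more tested members and were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Each camera call is printed with its value when the correlation was estimated per list. For each list, genes were also counted after adjustment over that list alone. Genes named in the text follow a rule fixed in the plan: the 8 most raised and 8 most lowered past the threshold with a mean of at least 5 CPM in the higher group and no overlap between groups, leaving out predicted genes, a few members of each list, and a fixed set of natriuretic peptide, myosin, actin, calcium pump, collagen, periostin and ERBB genes. Where a count of 5 or fewer list members is given with their names, names beyond this rule were chosen after their values were seen. A few genes that the rule selects are not reported here. Library measures were compared by exact two-sided permutation.

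The fit was tested on simulated data with 200 changed genes of 11018 in 10 simulations. For TAC saline against sham saline, 43.6% of 1.5-fold, 76.7% of 2-fold and 95.8% of 4-fold changes were recovered, with 3.81% false calls. For TAC NRG1 against TAC saline the values were 41.5%, 79.9%, 98.2% and 3.69%. Simulated genes varied independently, with the same spread in every group and no libraries that deviated together across genes. These rates therefore need not hold where real libraries do so. On simulated lists, whose genes varied independently of each other, camera called 10 of 10 moved lists and 1 of 30 unmoved lists. These lists do not give the error rate for real lists, whose members can be correlated. The comparisons share libraries, so their agreement was set against 100 simulated data sets and against 20 splits of the shared libraries.

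Alternatives fixed in the plan covered scaling, test, filter, mitochondrial genes, groups in the fit, replicate numbers, spread, threshold, list test and leaving out each library. Alternatives added after the data were seen were total reads as the only scaling and a transcript length trend removed per library. Thinning every library to the fewest reads and leaving out TAC NRG1 4 and 5, or another pair of that group, were also added then. Transcript lengths came from GENCODE vM21 on GRCm38 for 10906 of the tested genes. They were those of each gene's longest annotated transcript, which need not be the one expressed, so a length trend may be removed incompletely. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.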

Results

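Left ventricular RNA from male C57BL/6NRj mice was profiled by BRB-seq, a multiplexed assay that barcodes each RNA sample and reads the 3′ ends of its transcripts. The mice had sham surgery or transverse aortic constriction (TAC), a narrowing of the aorta that raises the pressure load on the left ventricle, and carried minipumps with saline or neuregulin-1β (NRG1), a growth factor ligand of the ERBB3 and ERBB4 receptors. There were 3 groups of 5 libraries: sham with saline, TAC with saline (TAC saline) and TAC with NRG1 (TAC NRG1). No sham group received NRG1, so the response to NRG1 was measured only under constriction. Whole reads recovered from the deposited log2 values summed to 2.02 to 5.62 M reads per library. Mean depth was 3.60 ± 0.55 M reads in sham, 3.42 ± 0.41 M in TAC saline and 3.33 ± 1.45 M in TAC NRG1 (SD, n = 5 each). The labels do not state that each library came from a separate mouse, so the p-values measure the spread between these samples. Levels are given in CPM (the deposited values taken out of the log and divided by 1000) on the authors' scaling as mean ± SD of 5 libraries, and fold changes are on the log2 scale with their standard error (SE) unless stated otherwise.

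Mitochondrial and blood transcripts were measured as shares of each library's reads. Mitochondrially encoded genes took 31.1% ± 0.47 of reads in sham, 27.7% ± 1.62 in TAC saline and 25.8% ± 2.35 in TAC NRG1 (SD, n = 5 each). The exact two-sided permutation test gave p = 0.0079, the smallest that 5 against 5 libraries allow, for each TAC group against sham (adjusted p = 0.0237 over 9 comparisons), and p = 0.190 between the TAC groups (adjusted p = 0.343). Haemoglobin genes took 0.142% ± 0.058, 0.131% ± 0.020 and 0.266% ± 0.086 of reads in the same order. The share was higher in all 5 TAC NRG1 libraries than in any TAC saline library (exact two-sided permutation p = 0.0079, adjusted p = 0.0237). Against sham the exact permutation adjusted p was 0.0713 for TAC NRG1 and 0.822 for TAC saline. Within TAC NRG1 it was 0.366% in library 4 and 0.350% in library 5, against 0.189% to 0.222% in the other 3. Libraries 4 and 5 were also the shallowest (2.02 and 2.13 M reads). In a principal component analysis, component 1 (27.5% of variance) placed sham libraries between -34.3 and -20.0 and TAC libraries between -6.12 and 30.1. On component 2 (14.5%), TAC NRG1 libraries 4 and 5 lay at 32.4 and 35.9, and the other 13 libraries between -17.5 and 3.30.

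**Figure D1:**
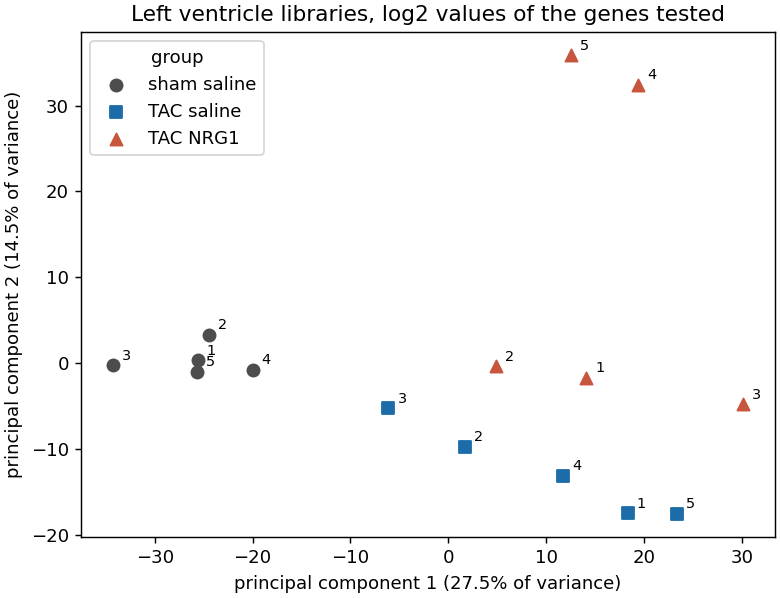
Position of each of the 15 libraries on principal components 1 (27.5% of variance) and 2 (14.5%), from the tested genes, coloured by group and marked with the replicate number. Sham libraries lie at -20.0 or below on component 1, and TAC NRG1 libraries 4 and 5 at 32.4 and 35.9 on component 2.

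TAC saline against sham saline asks what pressure overload alone does to the ventricle. Stress genes of cardiomyocytes rose: Acta1, the skeletal muscle actin of the fetal heart, from 565 ± 201 to 2814 ± 1095 CPM (4.94-fold), and Nppa, which encodes atrial natriuretic peptide, from 197 ± 23.2 to 657 ± 202 CPM (3.22-fold, n = 5 each). Matrix genes rose as well, with Postn, a matricellular protein of activated fibroblasts, at 35.0 ± 10.3 CPM in sham and 265 ± 138 CPM in TAC saline (6.80-fold). Mitotic genes were low in sham and rose, as for Top2a, a topoisomerase of dividing cells, from 2.04 ± 1.21 to 15.2 ± 9.77 CPM (7.23-fold). Genes of ion channels and fat oxidation were among those that fell, including Kcnv2, a modifier subunit of potassium channels, which fell by 1.98 ± 0.34 on the log2 scale. With limma, 1180 of 11018 genes passed an adjusted p of 0.05, 713 higher and 467 lower, and 204 of the higher and 17 of the lower genes changed by over 2-fold. At an unadjusted p under 0.05 there were 2662. Between the groups, 520 genes were higher and 406 lower with no overlap of the 5 and 5 libraries, 8.40% of genes, where chance gives 0.794%. With total reads as the only scaling the count was 1269 but 84.9% of it was higher, against 60.4% on the authors' scaling, and the median log2 fold change of all genes was then 0.10. The count was 630 without TAC saline 5 and 707 without TAC saline 1.

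Of the fetal and stress genes of cardiomyocytes, 16 of 17 tested members rose and none fell, with the same 16 past the threshold when adjusted over the list alone and a median log2 fold change of 0.88 (camera adjusted p = 6.9e-23, and adjusted p = 0.0204 with an estimated correlation). Myh7, the slow myosin heavy chain that the adult mouse ventricle largely replaces, rose by 1.70 ± 0.27, from 65.5 ± 18.3 to 214 ± 67.0 CPM (limma adjusted p = 0.000165). Nppb, which encodes brain natriuretic peptide, rose by 1.25 ± 0.20 and Ankrd1, a stretch-responsive sarcomere protein, 2.14-fold. Mybpc2, the fast skeletal myosin binding protein C, rose from 9.25 ± 3.15 to 25.7 ± 4.72 CPM. Myh6, the main adult myosin heavy chain, stood at 7027 ± 335 CPM in sham and 6407 ± 621 in TAC saline, a log2 difference of -0.14 ± 0.09 that did not pass (limma adjusted p = 0.388). Among 25 adult contractile and calcium handling genes, 4 rose and 5 fell (5 and 9 adjusted over the list alone), and the list itself was not called (limma camera adjusted p = 0.123). Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell by 0.46 ± 0.09 and Pln, its inhibitor phospholamban, fell by 0.42 ± 0.09. Of 21 ion channel genes 4 fell and 0 rose (9 lower adjusted over the list alone), with a list median of -0.32, or -0.21 with total reads as the only scaling and -0.20 without TAC saline 2 (camera adjusted p = 9.0e-05, and adjusted p = 0.0353 with an estimated correlation). Kcnj2, an inward rectifier potassium channel, fell by 0.71 ± 0.14.

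Extracellular matrix genes rose almost as a whole: 44 of 46 tested members passed and all 46 did when adjusted over the list alone, with a median log2 fold change of 1.34 (camera adjusted p = 1.7e-53, and adjusted p = 0.0353 with an estimated correlation). Tnc, a matrix glycoprotein of injured tissue, rose by 3.36 ± 0.46 and Timp1, an inhibitor of matrix metalloproteinases, by 2.88 ± 0.40. Tnc stood at 0.4488 to 1.445 CPM in sham, so its fold rests on few reads there. The fibrillar collagens Col1a1 and Col3a1 rose 3.24-fold and 3.34-fold, to 162 ± 54.2 and 550.0 ± 183 CPM. Fibroblast markers rose in 8 of 15 cases and Gsn fell (9 higher and 2 lower adjusted over the list alone), with the list called higher (camera adjusted p = 1.7e-05, and adjusted p = 0.0353 with an estimated correlation). Lum, a proteoglycan of fibroblasts, rose from 50.2 ± 6.56 to 108 ± 14.2 CPM. No smooth muscle or myofibroblast marker of 9 passed (2 higher adjusted over the list alone; limma camera adjusted p = 0.514). Of 11 pericyte markers Cspg4 rose and Abcc9 fell (2 and 1 adjusted over the list alone; limma camera adjusted p = 0.954).

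Of the cell cycle genes, 26 of 30 tested members rose (28 adjusted over the list alone), with a median log2 fold change of 2.04 (camera adjusted p = 1.7e-27, and adjusted p = 0.0353 with an estimated correlation). Ccnb1, the mitotic cyclin B1, rose by 3.59 ± 0.64 from 0.57 ± 0.44 CPM, so its fold rests on few reads in sham. Ckap2, Kif11 and Anln, proteins of the spindle and of cytokinesis, rose 7.95-fold, 7.92-fold and 6.53-fold. In sham they stood at 0.3957 to 1.983, 0.3335 to 1.068 and 0.7975 to 1.89 CPM, so these folds also rest on few reads. Genes of the integrated stress response and serine synthesis were called higher as a list with 3 of 15 members past the threshold, Mthfd2, Psat1 and Gdf15 (4 adjusted over the list alone; camera adjusted p = 0.00229, and adjusted p = 0.0353 with an estimated correlation). Psat1, an enzyme of serine synthesis, rose by 1.29 ± 0.31.

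Interferon response genes rose in 13 of 23 cases (18 adjusted over the list alone), with a median log2 fold change of 0.81 (camera adjusted p = 1.6e-12, and adjusted p = 0.0353 with an estimated correlation). Irf7, a transcription factor of the interferon response, rose from 6.34 ± 1.26 to 13.4 ± 3.02 CPM and Oasl2, an interferon-induced gene, from 5.95 ± 1.16 to 11.5 ± 1.87 CPM. Macrophage markers rose in 10 of 25 cases (14 adjusted over the list alone), with the list called higher (camera adjusted p = 3.6e-08), a call that was lost at adjusted p = 0.246 with an estimated correlation. Tyrobp, a signalling adaptor of myeloid cells, rose by 0.65 ± 0.14 and C1qa, a complement subunit made by macrophages, by 0.53 ± 0.13. Of 18 cytokine genes Cxcl10, Ccl8, Ccl2 and Ccl7 rose (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000395, and adjusted p = 0.211 with an estimated correlation). Ccl8, a monocyte chemoattractant, rose by 1.70 ± 0.37. Antigen presentation genes rose in 3 of 11 cases, Tap1, B2m and H2-D1 (4 adjusted over the list alone; camera adjusted p = 0.0271, and adjusted p = 0.577 with an estimated correlation). Reads of H2 genes can be split between near-identical copies, so H2-D1 is uncertain. B2m, the light chain of class I molecules, rose by 0.60 ± 0.11. The antigen presentation call was lost without sham saline 4, TAC saline 3 or TAC saline 4 (limma camera adjusted p of 0.0542 to 0.597), and with total reads as the only scaling (0.0502). Heat shock and immediate early genes were called higher with 5 of 16 past the threshold (5 adjusted over the list alone; camera adjusted p = 9.0e-05, and adjusted p = 0.246 with an estimated correlation). Its 5 members were chaperones of the cytosol, among them Hspb6, a small heat shock protein of muscle, which rose by 0.75 ± 0.08.

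Several lists of energy metabolism were called lower with the preset correlation, and 0 of them with an estimated one. Of 36 tested genes of fatty acid uptake and oxidation, 19 fell and 0 rose (25 adjusted over the list alone), with a median of -0.30, or -0.19 with total reads as the only scaling (camera adjusted p = 1.8e-13, and adjusted p = 0.116 with an estimated correlation). Ech1, an isomerase of unsaturated fatty acid oxidation, fell by 0.58 ± 0.09 and Acadm, the medium-chain acyl-CoA dehydrogenase, fell by 0.47 ± 0.09. Of 34 genes of the tricarboxylic acid cycle and of ketone or branched chain oxidation, 15 fell and 0 rose, with a median of -0.22, or -0.11 with total reads as the only scaling (23 lower and 1 higher adjusted over the list alone; camera adjusted p = 5.0e-13, and adjusted p = 0.147 with an estimated correlation). Of 71 nuclear genes of oxidative phosphorylation, 22 fell, with a median of -0.25, or -0.14 with total reads as the only scaling (52 adjusted over the list alone; camera adjusted p = 2.2e-20, and adjusted p = 0.246 with an estimated correlation). Sdha, a subunit of complex II, fell by 0.37 ± 0.08. The mitochondrially encoded mt-Nd2 and mt-Nd5 fell, 2 of 9 tested (4 adjusted over the list alone; camera adjusted p = 0.00213, and adjusted p = 0.116 with an estimated correlation). The share of reads from mitochondrial genes moved with these lists (31.1% in sham, 27.7% in TAC saline). Circadian clock genes were called lower with 2 of 18 past the threshold, among them Tef, a clock output factor (2 also when adjusted over the list alone; camera adjusted p = 0.0271, and adjusted p = 0.246 with an estimated correlation). That call was lost without sham saline 3 or TAC saline 1 (limma camera adjusted p of 0.0552 to 0.138). Glycolysis genes were not called as a list (Pfkp higher and Ldhb, Pdk2, Hk2 and Slc2a4 lower of 23; the counts were the same adjusted over the list alone; limma camera adjusted p = 0.386).

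Other genes with large falls and no overlap between groups were Inmt, an indolethylamine methyltransferase (-1.59 ± 0.33), Angpt1, an angiopoietin that stabilises vessels (-1.25 ± 0.25), Tbc1d10c (-1.14 ± 0.26), Dnaaf3, an assembly factor of ciliary dynein (-1.04 ± 0.23), and Ankrd24 (-1.11 ± 0.25). Retnla, a marker of alternatively activated macrophages, fell by 1.29 ± 0.34, but without TAC saline 5 its limma adjusted p was 0.0612. Ccl11, an eosinophil chemoattractant, fell by 1.03 ± 0.26. When the reads of all libraries were thinned to the fewest, Ccl11 and Ankrd24 were past the threshold no longer (limma adjusted p of 0.0544 and 0.0768). Endothelial markers were mixed, with Sox18 and Gpihbp1 higher and Aqp1 and Rgcc lower of 25 (3 higher and 2 lower adjusted over the list alone; limma camera adjusted p = 0.294). Aqp1, a water channel of endothelium, fell by 0.65 ± 0.16, with limma adjusted p = 0.0657 when a robust spread was used. The ERBB receptor genes did not pass: Erbb2 was at 6.52 ± 0.68 and 6.00 ± 0.49 CPM, Erbb3 at 7.76 ± 0.62 and 7.63 ± 2.02 CPM, and Erbb4 at 4.20 ± 1.65 and 2.44 ± 1.08 CPM in sham and TAC saline (limma adjusted p of 0.816, 0.888 and 0.180). No member of 15 tested in the ERBB list passed, also when adjusted over the list alone (limma camera adjusted p = 0.954). Haemoglobin Hbb-bs, whose reads can be split with its near-identical copy Hbb-bt, stood at 990 ± 383 and 842 ± 141 CPM (limma adjusted p = 0.699), and 0 of 6 blood transcripts passed (0 adjusted over the list alone; camera adjusted p = 0.808). Over the 21 lists not called, limma camera adjusted p ranged from 0.0597 to 0.954.

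**Figure D2:**
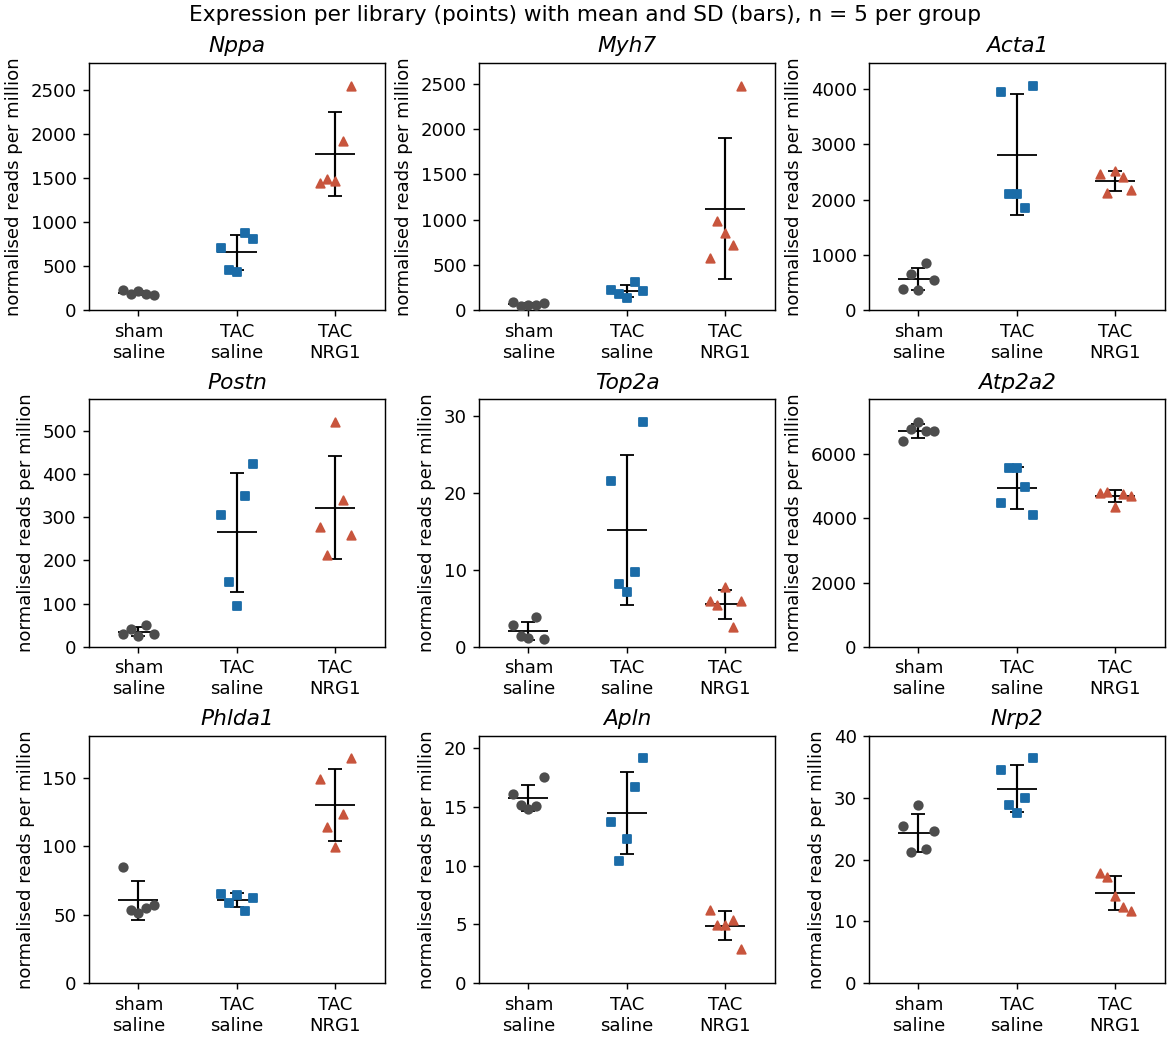
CPM in each library (points) with the mean ± SD (bars) of the 5 libraries per group for Nppa, Myh7, Acta1, Postn, Top2a, Atp2a2, Phlda1, Apln and Nrp2. Mean Nppa was 197, 657 and 1773 CPM and mean Apln 15.8, 14.4 and 4.87 CPM in sham saline, TAC saline and TAC NRG1.

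TAC NRG1 against TAC saline asks what the factor adds in the overloaded ventricle. Myh7 rose from 214 ± 67.0 to 1121 ± 773 CPM (4.71-fold), and Nppa rose from 657 ± 202 to 1773 ± 475 CPM (2.74-fold, n = 5 each). Within TAC NRG1, Myh7 stood at 2478 CPM in library 5 and at 576.5 to 985.5 CPM in the others. Phlda1, an early target of ERK signalling, rose from 60.6 ± 5.03 to 130.2 ± 26.2 CPM (2.12-fold). Apln, the vascular peptide apelin, fell by 1.58 ± 0.20 on the log2 scale, from 14.4 ± 3.49 to 4.87 ± 1.23 CPM, and Nrp2, a co-receptor of vascular endothelial growth factors and semaphorins, fell by 1.12 ± 0.14, from 31.5 ± 3.82 to 14.6 ± 2.77 CPM. With limma, 143 of 11018 genes passed, 74 higher and 69 lower, with 12 higher and 15 lower by over 2-fold and 1691 at an unadjusted p under 0.05. There were 199 genes higher and 138 lower with no overlap between the groups, 3.06% of genes, where chance gives 0.794%. The count depended on single libraries: it was 78 without TAC saline 1, 92 without TAC saline 4, 93 without TAC saline 5, 58 without TAC NRG1 4 and 74 without TAC NRG1 5, and rose to 221 without TAC NRG1 2. It was 39 without TAC NRG1 4 and 5 together, of which 36 were among the 143. Other pairs of TAC NRG1 libraries left out gave 41 (3 and 5) to 124 (2 and 5) where 4 or 5 was 1 of the pair, and 378 to 388 where neither was. It was 77 when only these 2 groups were fitted.

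Besides Myh7 and Nppa, Syt12, a synaptotagmin, rose from 3.29 ± 0.91 to 9.60 ± 2.80 CPM (limma adjusted p = 0.00472). Bcr, the breakpoint cluster region kinase, rose by 1.32 ± 0.25, with 36.6 CPM in TAC NRG1 3 and 14.5 to 16.6 CPM in the other 4. Lower in TAC NRG1 were Mest, an imprinted gene (-1.53 ± 0.25), Il6ra, the interleukin-6 receptor (-1.52 ± 0.31), Slc26a6, an anion exchanger (-1.22 ± 0.27), Bcl6b, an endothelial repressor of transcription (-1.19 ± 0.24), Pcdh12, an endothelial protocadherin (-1.17 ± 0.23), and Pld2, a phospholipase D (-1.11 ± 0.25). Mest stood at 45.8 ± 23.0 CPM in TAC saline and 12.7 ± 2.14 in sham. Il6ra was at 1.16 and 2.43 CPM in TAC NRG1 4 and 5 and at 4.28 to 5.83 CPM in the other 3, and without the former 2 its value was -0.90 (limma adjusted p = 0.0798). With a robust spread Bcl6b passed no longer (limma adjusted p = 0.0557). Slc26a6 was past the threshold no longer without TAC saline 4 or TAC NRG1 5 (limma adjusted p of 0.0501 to 0.0543), and Pld2 without TAC saline 1, TAC saline 5, TAC NRG1 4 or TAC NRG1 5 (0.0502 to 0.0680). Slc27a1 and Hba-a2, named below as past the threshold, were not checked with libraries left out. Of 36 named genes past the threshold in this contrast that were checked in this way, 14 passed whichever library was left out: Myh7, Syt12, Nppa, Bcr, Phlda1, Apln, Mest, Il6ra, Bcl6b, Pcdh12, Nrp2, Meox2, Pfkp and Nqo1. Without TAC NRG1 4 and 5 together, 8 of the 36 passed with limma: Myh7 (1.93), Nppa (1.22), Bcr (1.46), Phlda1 (0.98), Apln (-1.40), Mest (-1.79), Slc26a6 (-1.14) and Nrp2 (-0.94). The others then had adjusted p of 0.0561 (Cdh5) to 0.395 (Tpi1, whose value went from 0.33 to 0.20).

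Among the 17 fetal and stress genes tested, Myh7, Nppa and Ankrd1 rose and Mybpc2 fell (6 higher and 2 lower adjusted over the list alone), and the list was called higher (camera adjusted p = 0.00346, and adjusted p = 0.437 with an estimated correlation). Ankrd1 rose by 0.59 ± 0.13 to 1777 ± 234 CPM, and Mybpc2 fell by 0.72 ± 0.18 to 15.5 ± 1.98 CPM. Without TAC saline 2, 3 or 4 or TAC NRG1 5, Ankrd1 had a limma adjusted p of 0.0516 to 0.0631, and with a robust spread 0.0765. Mybpc2 had 0.0502 to 0.130 without TAC saline 1, 2, 4 or 5 or TAC NRG1 2, 3, 4 or 5. The list call was lost without TAC NRG1 3 (limma camera adjusted p = 0.0725). Nppb was at 1411 ± 432 and 1599 ± 285 CPM, Acta1 at 2814 ± 1095 and 2340 ± 179 CPM and Myh6 at 6407 ± 621 and 5535 ± 592 CPM in TAC saline and TAC NRG1, and none of the 3 passed (limma adjusted p of 0.645, 0.712 and 0.266). Of 25 adult contractile genes Tnnt2, cardiac troponin T, rose by 0.35 ± 0.08 (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.868), a call lost without TAC saline 1, 4 or 5 or TAC NRG1 4 or 5 (limma adjusted p of 0.0659 to 0.109). Atp2a2 did not pass, at 4946 ± 648 and 4696 ± 190 CPM (limma adjusted p = 0.770). Nppa was also the member of the atrial list that passed (1 of 5, also adjusted over the list alone; camera adjusted p = 0.0192, and adjusted p = 0.128 with an estimated correlation).

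Col1a1 was at 162 ± 54.2 and 198 ± 79.3 CPM and Postn at 265 ± 138 and 323 ± 120 CPM in TAC saline and TAC NRG1, and neither passed (limma adjusted p of 0.536 and 0.529). Of 46 matrix genes Thbs4, a thrombospondin of stressed muscle, rose by 1.16 ± 0.27, 1 of 2 members past the threshold (3 adjusted over the list alone). The list was called higher (camera adjusted p = 0.00346, and adjusted p = 0.667 with an estimated correlation), a call lost without TAC saline 2, TAC saline 3 or TAC NRG1 3 (0.0845 to 0.615). Thbs4 lost its call without TAC saline 2 or 3 or TAC NRG1 3 or 4 (limma adjusted p of 0.0573 to 0.0851) and with a robust spread (0.147). No fibroblast marker of 15 passed, also when adjusted over the list alone (limma camera adjusted p = 0.993).

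Endothelial markers were called lower, with Meox2 and Cdh5 past the threshold of 25 tested (7 lower and 2 higher adjusted over the list alone) and a median of -0.18 (camera adjusted p = 0.00143, and adjusted p = 0.118 with an estimated correlation). Meox2, a homeobox factor of endothelium, fell by 0.81 ± 0.17, and Cdh5, the cadherin of endothelial junctions, fell by 0.43 ± 0.09. Cdh5 had a limma adjusted p of 0.0510 to 0.0582 without TAC saline 1 or 5. Angiogenic factors were also called lower, with Apln and Nrp2 lower and Fgf1, a fibroblast growth factor, higher by 0.35 ± 0.08 of 17 tested (4 lower and 1 higher adjusted over the list alone). Their median was -0.14, and -0.22 to -0.25 without TAC saline 2, TAC NRG1 3 or TAC NRG1 5 (camera adjusted p = 0.0359, and adjusted p = 0.170 with an estimated correlation), and the call was lost without TAC saline 4 or TAC NRG1 4 (0.0669 to 0.0736) and with thinned reads (0.0653). Fgf1 lost its call without TAC saline 1 or 3 or TAC NRG1 2 or 4 (limma adjusted p of 0.0502 to 0.0851).

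Interferon response genes lay lower in TAC NRG1 than in TAC saline, with a median of -0.54 and Gbp3, Oasl2 and Gbp7 past the threshold of 23 tested (13 adjusted over the list alone; camera adjusted p = 1.9e-10, and adjusted p = 0.128 with an estimated correlation). Oasl2 fell by 0.78 ± 0.19 to 6.67 ± 0.99 CPM, near its 5.95 ± 1.16 in sham. Gbp3 and Gbp7, guanylate-binding proteins whose reads can be shared among close relatives and whose split is uncertain, fell by 0.83 ± 0.20 and by 0.76 ± 0.19. These calls were lost for Oasl2 without TAC saline 2, 4 or 5 or TAC NRG1 1, 3, 4 or 5 (limma adjusted p of 0.0512 to 0.110). They were lost for Gbp3 without TAC saline 4 or 5, TAC NRG1 2, 3, 4 or 5 or sham saline 1 (0.0506 to 0.122), and for Gbp7 without TAC saline 2, 3, 4 or 5, TAC NRG1 1, 3, 4 or 5 or sham saline 2 or 4 (0.0534 to 0.125). No antigen presentation gene of 11 passed (7 lower adjusted over the list alone), while the list was called lower with a median of -0.43, or -0.23 without TAC saline 4 (camera adjusted p = 8.9e-06, and adjusted p = 0.251 with an estimated correlation). B2m was at 809.6 ± 180 CPM in TAC saline, with 1125 in TAC saline 4, and 609 ± 84.8 CPM in TAC NRG1 (limma adjusted p = 0.0752), and it passed with the length trend removed (-0.52, limma adjusted p = 0.0219). Of 18 cytokine genes Il6ra and Cxcl9, a chemokine induced by interferon-γ, were lower (3 adjusted over the list alone; limma camera adjusted p = 0.800). Cxcl9 lost its call without any of 12 libraries, TAC saline 1 to 5, TAC NRG1 1, 3 or 4 or sham saline 1, 2, 4 or 5 (limma adjusted p of 0.0521 to 0.0978). Macrophage markers were called lower with 0 of 25 past the threshold (0 adjusted over the list alone; camera adjusted p = 0.0134, and adjusted p = 0.639 with an estimated correlation), a call lost without TAC saline 4 or TAC NRG1 2 (0.352 to 0.427) and with thinned reads (0.0748).

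Cell cycle genes were called lower, with all 30 members below 0, a median of -0.74 (-0.46 without TAC saline 5) and Cenpf, a kinetochore protein, past the threshold (14 adjusted over the list alone; camera adjusted p = 2.5e-11, and adjusted p = 0.199 with an estimated correlation). Cenpf fell by 1.12 ± 0.24, and without TAC saline 1, TAC saline 5 or TAC NRG1 4 its limma adjusted p was 0.0501 to 0.0630. Heat shock and immediate early genes were called lower with Jun, an AP-1 transcription factor, past the threshold of 16 (2 adjusted over the list alone; camera adjusted p = 0.0469, and adjusted p = 0.588 with an estimated correlation). Jun fell by 0.76 ± 0.16, with limma adjusted p of 0.0596 without TAC NRG1 4 and 0.0627 under a robust spread. The list call was lost without TAC saline 1, 3 or 4 or TAC NRG1 2, 4 or 5 (0.0669 to 0.192), with thinned reads (0.108) and with a filter of 5 CPM (0.0564). Without TAC NRG1 4 and 5 together the median was 0.01 (limma camera adjusted p = 0.731). ERK target genes were not called (limma camera adjusted p = 0.319), with Phlda1 and Etv5, an ETS factor, higher of 23 (2 higher and 1 lower adjusted over the list alone). Etv5 rose from 8.67 ± 2.52 to 14.4 ± 1.37 CPM, a call lost without TAC saline 1, 3 or 4, TAC NRG1 2, 3, 4 or 5 or sham saline 4 (limma adjusted p of 0.0502 to 0.125). Erbb2 was at 6.00 ± 0.49 and 6.32 ± 2.08 CPM, Erbb3 at 7.63 ± 2.02 and 9.60 ± 0.95 CPM and Erbb4 at 2.44 ± 1.08 and 3.16 ± 1.82 CPM, and none passed (limma adjusted p of 0.995, 0.347 and 0.707). The ERBB list had 0 of 15 past the threshold (0 adjusted over the list alone; limma camera adjusted p = 0.573).

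Blood cell transcripts rose by close to 1 log2 unit, 5 of 6 tested (5 adjusted over the list alone), with a median of 1.00, or 0.66 without TAC NRG1 4 and 5 (camera adjusted p = 2.8e-09, and adjusted p = 0.128 with an estimated correlation). They were Alas2, the haem synthesis enzyme of red cells (1.06 ± 0.23), Hbb-bt (1.05 ± 0.22), Hba-a1 (1.03 ± 0.22), Hbb-bs (0.97 ± 0.21) and Hba-a2. The Hba-a2 call was not checked with libraries left out. The split of reads between the near-identical haemoglobin copies is uncertain. Alas2 and Hba-a1 lost their calls without TAC NRG1 4 or 5 (limma adjusted p of up to 0.0667), Hbb-bs without either of those or TAC saline 4 (up to 0.0664) and Hbb-bt without TAC NRG1 4 (0.0510). With a robust spread these 4 genes passed no longer (limma adjusted p of 0.0677 to 0.123). Without TAC NRG1 4 and 5 together their values were 0.64 (Hbb-bs) to 0.75 (Hbb-bt), with limma adjusted p of 0.1625 to 0.195. Ribosomal protein genes were called higher, with 81 of 83 above 0 and a median of 0.22 (0.13 without TAC NRG1 4 and 5 and 0.12 with the length trend removed), although Rpsa (0.32 ± 0.07) was the 1 member past the threshold (39 adjusted over the list alone; camera adjusted p = 3.1e-25, and adjusted p = 0.128 with an estimated correlation). Rpsa had a limma adjusted p of 0.0501 to 0.0606 without TAC saline 4, TAC NRG1 4 or TAC NRG1 5. Relative to the TAC saline mean, the list's mean log2 level was 0.33 and 0.41 in TAC NRG1 4 and 5 and 0.11 to 0.15 in the other 3, so it moved with those 2 libraries and with their haemoglobin share.

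Glycolysis genes were called higher with Pfkp and Tpi1 past the threshold of 23 (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000247, and adjusted p = 0.128 with an estimated correlation). Pfkp, a phosphofructokinase isoform, rose by 0.60 ± 0.12 to 65.4 ± 10.3 CPM, and Tpi1, triosephosphate isomerase, by 0.33 ± 0.08. Tpi1 lost its call without any of 9 libraries, TAC saline 1, 2, 4 or 5, TAC NRG1 4 or 5 or sham saline 1, 4 or 5 (limma adjusted p of 0.0521 to 0.154). Nuclear genes of oxidative phosphorylation were called higher with a median of 0.13, or 0.19 without TAC saline 3 or TAC NRG1 3, and 0 of 71 past the threshold (0 adjusted over the list alone; camera adjusted p = 9.4e-09, and adjusted p = 0.588 with an estimated correlation), and without TAC NRG1 4 and 5 the median was 0.02 (0.296). With the transcript length trend of each library removed it was also 0.02 (0.164). Proteasome genes (median 0.08, 0 of 26; 0 adjusted over the list alone) were called higher as well (camera adjusted p = 0.00556, and adjusted p = 0.153 with an estimated correlation), a call lost with the length trend removed (median 0.02, 0.316). Genes of the oxidative stress response were called higher with Nqo1, a quinone reductase, past the threshold (0.48 ± 0.10; 3 higher and 1 lower of 20 adjusted over the list alone; camera adjusted p = 0.0130, and adjusted p = 0.361 with an estimated correlation), and not without TAC NRG1 3 (0.0929). Endoplasmic reticulum chaperones were called higher with 0 of 18 past the threshold (2 adjusted over the list alone; camera adjusted p = 0.0301, and adjusted p = 0.251 with an estimated correlation), and not without TAC saline 4, TAC NRG1 3 or TAC NRG1 5 (0.0585 to 0.129), with thinned reads (0.124) or with a filter of 5 CPM (0.0789). Srebf1, a regulator of lipid synthesis, rose by 0.53 ± 0.12 and was the member past the threshold of 14 fatty acid synthesis genes (1 adjusted over the list alone; camera adjusted p = 0.524), with limma adjusted p of 0.0549 to 0.0874 without TAC saline 1, TAC NRG1 4 or TAC NRG1 5. Of 36 genes of fatty acid oxidation Slc27a1, a fatty acid transporter, was higher (1 higher and 2 lower adjusted over the list alone; limma camera adjusted p = 0.170). The Slc27a1 call was not checked with libraries left out. The 20 lists not called had camera adjusted p of 0.170 to 0.993, and 0 of the 17 called lists held with an estimated correlation.

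**Figure D3:**
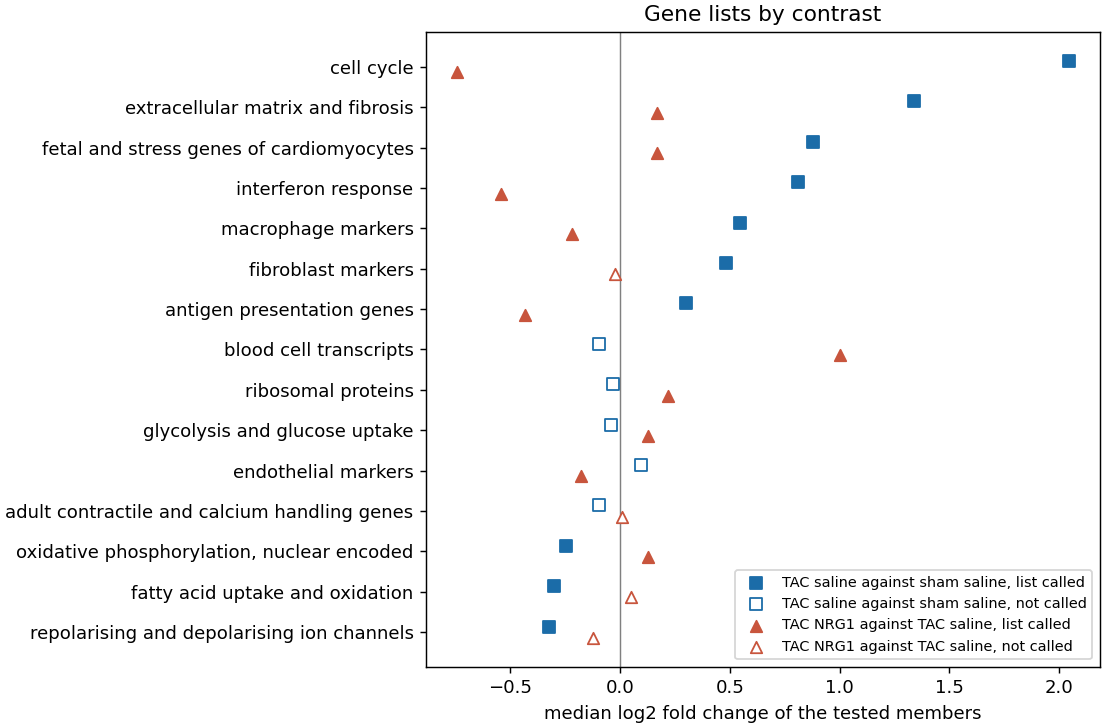
Median log2 fold change of 15 gene lists in TAC saline against sham saline and in TAC NRG1 against TAC saline, with filled points for lists called by camera at a preset correlation of 0.01. None of the calls in TAC NRG1 against TAC saline held with an estimated correlation, and the cell cycle list had medians of 2.04 and -0.74. The comparisons share the TAC saline libraries with opposite signs, which favours medians of opposite sign. The lists were not checked with these libraries split.

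TAC NRG1 against sham saline joins both changes. Nppa rose from 197 ± 23.2 to 1773 ± 475 CPM (8.83-fold) and Myh7 from 65.5 ± 18.3 to 1121 ± 773 CPM (15.3-fold, n = 5 each). Tnc rose by 4.42 ± 0.46 on the log2 scale and Timp1 by 4.38 ± 0.40. In TAC NRG1 3, Timp1 stood at 336 CPM, against 43.2 to 85.0 CPM in the other 4. Tnc stood at 90.55 CPM in the same library and at 7.735 to 21.59 CPM in the other 4. Its sham values of 0.4488 to 1.445 CPM rest on few reads. Kcnv2 fell by 2.22 ± 0.34. With limma, 1777 of 11018 genes passed, 963 higher and 814 lower, with 237 higher and 85 lower by over 2-fold and 3179 at an unadjusted p under 0.05. There were 686 genes higher and 600 lower with no overlap, 11.7% of genes, where chance gives 0.794%. With total reads as the only scaling 75.9% of 1798 genes were higher, against 54.2% on the authors' scaling.

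Fetal and stress genes rose in 16 of 17 cases (16 adjusted over the list alone; camera adjusted p = 2.5e-22, and adjusted p = 0.0219 with an estimated correlation), the 1 list of 17 called whose call held with an estimated correlation. Acta1 rose 4.34-fold, Ankrd1 3.22-fold and Nppb 2.76-fold. Sprr1a, a stress-induced proline-rich protein, rose by 3.96 ± 0.63 with 95.9 CPM in TAC NRG1 3 and 7.57 to 16.5 CPM in the other 4. In sham it stood at 0.4488 to 2.073 CPM, so its fold rests on few reads there. Nmrk2, a muscle kinase of nicotinamide riboside, rose by 3.24 ± 0.40. Matrix genes rose in 45 of 46 cases (45 adjusted over the list alone; camera adjusted p = 6.3e-50, and adjusted p = 0.0709 with an estimated correlation). Among them were Postn (3.18 ± 0.29), Cthrc1, a collagen triple helix protein (3.26 ± 0.51), Col12a1 (3.18 ± 0.56), Thbs4 (2.98 ± 0.27), Cilp (2.62 ± 0.25) and Col1a1 (1.99 ± 0.21). In sham Cthrc1 stood at 0.4785 to 1.646 CPM and Col12a1 at 0.1496 to 2.073 CPM, so their folds rest on few reads there. Fibroblast markers were called higher with 7 higher and 3 lower of 15 (9 and 3 adjusted over the list alone; camera adjusted p = 0.000636, and adjusted p = 0.175 with an estimated correlation), and Lum rose by 1.32 ± 0.12. Cell cycle genes rose in 16 of 30 cases and Cenpf fell (23 higher and 1 lower adjusted over the list alone; camera adjusted p = 6.3e-09, and adjusted p = 0.264 with an estimated correlation), with Anln at 1.32 ± 0.44 and 4.97 ± 1.75 CPM. Aldh1a2, a retinoic acid enzyme of the epicardium, rose from 5.81 ± 1.25 to 29.1 ± 21.4 CPM as the member past the threshold of 5 epicardial genes (1 adjusted over the list alone; limma camera adjusted p = 0.0923).

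Myh6 fell by 0.35 ± 0.09 in this contrast and Atp2a2 fell by 0.52 ± 0.09, with 4 higher and 7 lower of 25 adult contractile genes (5 and 8 adjusted over the list alone; limma camera adjusted p = 0.191). Of 21 ion channel genes 7 fell and 2 rose (13 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.000981, and adjusted p = 0.104 with an estimated correlation). Kcnip2, a subunit of the transient outward current, fell by 0.95 ± 0.16. Of 36 genes of fatty acid oxidation 17 fell and Angptl4 rose (19 and 1 adjusted over the list alone; camera adjusted p = 9.4e-08, and adjusted p = 0.264 with an estimated correlation), and Ppargc1a, a coactivator of mitochondrial genes, fell by 0.88 ± 0.15. Of 34 tricarboxylic acid cycle and related genes 17 fell and Bdh1 rose (23 and 1 adjusted over the list alone; camera adjusted p = 2.3e-08, and adjusted p = 0.264 with an estimated correlation). Nuclear oxidative phosphorylation genes fell in 8 of 71 cases, with a median of -0.13, or -0.03 with total reads as the only scaling, -0.22 without TAC NRG1 4 and 5 and -0.08 without TAC NRG1 3 (7 adjusted over the list alone; camera adjusted p = 5.9e-05, and adjusted p = 0.523 with an estimated correlation). Of 9 mitochondrially encoded genes 4 fell (4 adjusted over the list alone; camera adjusted p = 0.00383, and adjusted p = 0.175 with an estimated correlation). The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 fell by 1.04 ± 0.18 and by 1.15 ± 0.27, and without TAC NRG1 4 and 5 by 0.66 and by 0.46, while the mitochondrial share of reads was 31.1% in sham and 25.8% in TAC NRG1.

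Ribosomal protein genes rose in 20 of 83 cases, with a median of 0.17, or 0.06 without TAC NRG1 4 and 5 and 0.26 with total reads as the only scaling (22 adjusted over the list alone; camera adjusted p = 3.2e-09, and adjusted p = 0.312 with an estimated correlation), and Rpl3 at 124 ± 8.48 and 241 ± 21.5 CPM. Blood cell transcripts rose in 6 of 6 cases, with a median of 0.94, or 0.61 without TAC NRG1 4 and 5 (6 adjusted over the list alone; camera adjusted p = 5.9e-05, and adjusted p = 0.264 with an estimated correlation), while the haemoglobin share of reads did not pass. Hba-a1, uncertain for its near-identical copy, rose by 0.97 ± 0.22, and without TAC NRG1 4 and 5 its value was 0.60 (limma adjusted p = 0.0552). ERK target genes were called higher with Phlda1 (1.11 ± 0.13), Etv5 (1.08 ± 0.20) and Ier3 past the threshold of 23 (3 adjusted over the list alone; camera adjusted p = 0.0224, and adjusted p = 0.312 with an estimated correlation). That call was lost without TAC NRG1 1 or sham saline 2 (0.0731 to 0.0836). Endoplasmic reticulum chaperones were called higher with 6 of 18 (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0151, and adjusted p = 0.238 with an estimated correlation). Angiogenic factors fell in 5 of 17 cases, Apln (-1.73 ± 0.20), Nrp2 (-0.75 ± 0.14), Angpt1, Nrp1 and Dll4 (6 adjusted over the list alone, camera adjusted p = 0.0254, and adjusted p = 0.175 with an estimated correlation). The median of this list was -0.0878, and 0.0054 with total reads as the only scaling. It was -0.0544 without sham saline 4 and -0.2923 without TAC NRG1 1. Macrophage markers (3 higher of 25, Cd68, Laptm5 and C1qa, and 0 adjusted over the list alone) and cytokines (7 higher of 18 and Il6ra lower, and 8 and 2 adjusted over the list alone) were called higher. Their camera adjusted p was 0.00248 and 0.00863, with adjusted p = 0.486 and adjusted p = 0.312 with an estimated correlation, and without TAC NRG1 3 it was 0.0502 for both. The integrated stress response and serine one carbon genes were called higher with 4 of 15 (5 adjusted over the list alone; camera adjusted p = 0.0309, and adjusted p = 0.175 with an estimated correlation), but not without TAC NRG1 3 (0.0689), with total reads as the only scaling (0.0588) or with the length trend removed (0.0897). Interferon response genes were not called, with Ifi27l2a and Irf9 higher of 23 (1 adjusted over the list alone; limma camera adjusted p = 0.0923).

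Other genes past the threshold with no overlap were Pfkp (1.37 ± 0.12), Nqo1 (0.69 ± 0.10) and Gpx3, an extracellular glutathione peroxidase (0.98 ± 0.17), and, lower, Rtn4r, a receptor for myelin proteins (-2.11 ± 0.40), Myoc, myocilin (-2.11 ± 0.39), Inmt (-2.09 ± 0.33) and Klhl33 (-1.75 ± 0.32). Cdh4, retinal cadherin, fell by 1.93 ± 0.51, and by 1.17 without TAC NRG1 5, with limma adjusted p = 0.0537 under a robust spread and 0.0991 with thinned reads. Glycolysis genes rose in 9 and fell in 5 of 23 cases (10 and 6 adjusted over the list alone; limma camera adjusted p = 0.166). Erbb2, Erbb3 and Erbb4 did not pass (limma adjusted p of 0.795, 0.288 and 0.451), and Hbegf rose and Egf and Grb2 fell among 15 ERBB list members (2 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.657). The 20 lists not called had limma camera adjusted p of 0.0920 to 0.785.

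The TAC contrasts against sham shared their sham libraries. Both called 490 genes higher and 279 lower, where independent lists of those sizes would share 62.3 and 34.5, an expectation that leaves out the shared sham libraries. With the sham libraries split between the contrasts the means were 189.7 and 57.6 genes over 20 splits, against 17.5 and 4.28 for independent lists. The covariance of the log2 fold changes across genes was 0.122, against 0.0247 in simulations with no effect, and 0.101 with the sham libraries split. Genes are not independent replicates in these correlations. A further 1 gene, Rnf213, was higher in TAC saline and lower in TAC NRG1, and 1, Lrg1, was lower in TAC saline and higher in TAC NRG1, against sham. Both were named after their values were seen.

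Whether NRG1 moved the constriction response back was tested across genes. Of the 713 genes higher in TAC saline than in sham, 56.9% had a lower value in TAC NRG1 than in TAC saline, and of the 467 lower genes 64.5% had a higher value. As the TAC saline libraries enter both contrasts, simulations with no NRG1 effect gave 61.8% ± 16.2 and 67.2% ± 14.3 (SD over 100 simulations). With the TAC saline libraries split between the contrasts the shares were 49.3% ± 12.7 and 51.3% ± 14.2 (SD over 20 splits). The covariance of the constriction and NRG1 effects was -0.0239, against -0.0232 ± 0.0088 in simulations with no effect, and -0.0031 ± 0.0169 with the libraries split. A net shift of the constriction response in either direction was therefore not detectable with these libraries. The split covariance was -0.0211 without TAC saline 3, and the split share of lower genes was 34.2% without TAC saline 5. Single genes went both ways. Of the 713 higher genes 15 rose and 18 fell with NRG1, and of the 467 lower genes 3 rose and 1 fell, a tally in which the shared TAC saline libraries favour moves back. Nppa, Myh7 and Ankrd1 were among the 15, and Mest, Mybpc2 and Oasl2 among the 18.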

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

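The results here were picked by a fixed gap rule, and no test was chosen after they were seen. In each group of 5 libraries, a value was picked where its gap to the nearest other library was over 0.71 of the group's range. Gaps and ranges were taken on log2 values for genes and on unlogged values for library measures. The levels below are printed in CPM, on which the same rule could pick other values. Of 282 groups (91 genes and 3 library measures in 3 groups) 14 were picked, 4.97%, where chance alone picks about 1 in 20, or 14.1. TAC NRG1 3 held 4 of them.

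In TAC NRG1 3, Bcr was at 36.55 CPM (others 14.5 to 16.6), Kcnip2 at 49.29 (others 89.9 to 98.4), Irf7 at 7.514 (others 8.98 to 9.66) and Atp2a2 at 4364 (others 4713 to 4835). In TAC NRG1 5, Ckap2 was at 1.989 CPM (others 3.48 to 4.20) and Erbb4 at 6.409 (others 2.07 to 2.55). In TAC NRG1 2, Gbp7 was at 11.57 CPM (others 8.53 to 9.06) and Hspb6 at 1582 (others 1773 to 1840). In TAC saline 4, B2m was at 1125 CPM (others 677 to 767), and in TAC saline 3, Tpi1 was at 335.1 (others 283 to 296). In sham saline 4, Mybpc2 was at 14.8 CPM (others 7.01 to 8.45) and Pln at 5056 (others 5359 to 5459). Col3a1 was at 115.6 CPM in sham saline 3 (others 163 to 180), and Phlda1 at 85.05 in sham saline 1 (others 51.5 to 57.3).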

How the results depend on the processing

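Total-reads scaling, leaving out TAC NRG1 4 and 5 or another pair of that group, thinned reads and the length trend were chosen after the result was seen. The rest were planned. The planned edgeR fit and DESeq2 Wald test were not run, and limma-voom on recovered reads stood in. No named gene past the threshold changed sign; 16 of 3696 named gene comparisons did, all past no threshold. Medians of called lists moved over 1.5-fold with the call kept in 59 of 1148 comparisons, 32 farther from 0 and 27 nearer. These moves fell on 26 of the 50 list calls. The medians of 2 called lists changed sign: heat shock and immediate early genes in TAC NRG1 against TAC saline (0.0133 without TAC NRG1 4 and 5) and angiogenic factors in TAC NRG1 against sham saline (0.0054 with total reads). The cause was not tested. The count for TAC NRG1 against TAC saline (143) was 77 with only its 2 groups fitted and 39 without TAC NRG1 4 and 5; the cause was not tested. At a threshold of 0.01, which calls fewer genes by construction, counts were 505 for TAC saline against sham saline, 39 for TAC NRG1 against TAC saline and 849 for TAC NRG1 against sham saline. Lists called with an estimated correlation were 7, 0 and 1 in that order (16, 17 and 17 with the preset), and fry called 8 for TAC NRG1 against TAC saline; the cause was not tested. With 1 library left out, counts were 630 to 1500, 58 to 221 and 1346 to 1865, the split covariance was -0.0211 to 0.0085 and the split share of lower genes moved back was 34.2% to 62.3%; the cause was not tested. The 133 named gene values span the 3 comparisons and include values past no threshold. In TAC NRG1 against TAC saline, 8 of 36 such values past the threshold stayed past it without TAC NRG1 4 and 5. Of all 133 values, 29 were past the threshold no longer without those 2 libraries, and fewer under the other settings. These were 1 with upper-quartile scaling (Cxcl9) and 2 under voom (Gbp7 and Cxcl9). With no filter they were 7: Tnnt2, Tpi1, Etv5, Oasl2, Gbp3, Gbp7 and Cxcl9. With only 2 groups they were 14, the same 7 and Slc26a6, Pld2, Thbs4, Cenpf, Srebf1, Fgf1 and Rpsa. Under a robust spread they were 10: Aqp1, Alas2, Hbb-bt, Hba-a1, Hbb-bs, Bcl6b, Ankrd1, Thbs4, Jun and Cdh4. With total reads they were 6: Ankrd1, Mybpc2, Thbs4, Tpi1, Etv5 and Gbp3. With thinned reads they were 15: Ankrd24, Ccl11, Pld2, Mybpc2, Cdh5, Tpi1, Etv5, Cenpf, Srebf1, Oasl2, Gbp3, Gbp7, Cxcl9, Fgf1 and Cdh4. With the length trend removed Tpi1 and Gbp7 passed no longer, and B2m, the 1 gain under any setting, passed in TAC NRG1 against TAC saline (limma adjusted p = 0.0219). Of 50 list calls, 42 were lost with an estimated correlation, 13 under fry, 4 with thinned reads (macrophage, endoplasmic reticulum chaperone, heat shock and angiogenic lists of TAC NRG1 against TAC saline), 3 with the length trend removed, and 2 each at 5 CPM, with total reads and without TAC NRG1 4 and 5. The replicate numbers did not pair the libraries: same-number residuals had a mean correlation of -0.0066 over 15 pairs (-0.246 to 0.0795), and 2 of 15 libraries correlated best with their own number. With the replicate block, counts were 1049, 111 and 1645, all 50 list calls stayed, and 7 named genes of TAC NRG1 against TAC saline passed no longer: Mybpc2, Tnnt2, Tpi1, Etv5, Oasl2, Gbp3 and Cxcl9 (limma adjusted p of 0.0546 to 0.0897).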

Other observations

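The genes in this part, the test of TAC NRG1 4 and 5 alone, the depth tests over genes with many reads and on squared distance and the test of fewer endothelial cells were chosen after the result was seen. Prkar1a, a regulatory subunit of protein kinase A, rose in TAC NRG1 from 371 ± 33.9 to 612 ± 51.3 CPM (SD, n = 5 each; log2 0.72, limma adjusted p = 2.5e-05), with 308 ± 39.2 in sham. It passed whichever library was left out, with a highest adjusted p of 0.000157. Lrg1, a secreted glycoprotein that acts on vessels, was lower in TAC saline than in sham (29.2 ± 2.20 and 39.2 ± 5.70 CPM) and reached 51.3 ± 7.87 CPM in TAC NRG1 (limma adjusted p = 0.000333). Rnf213, a large ubiquitin ligase, was at 17.5 ± 1.52 CPM in sham, 25.5 ± 5.14 in TAC saline and 13.1 ± 1.02 in TAC NRG1 (limma adjusted p = 0.000226 between the TAC groups). Without TAC NRG1 4 and 5, the 3 genes had limma adjusted p of 0.00024, 0.00868 and 0.00221. Of 3 others looked at in the same way, Des (0.37), Fscn1 (-0.58) and Icam2 (-0.62) passed with limma adjusted p of 0.0254, 0.0230 and 0.0230. They lost the call without any of 5, 4 and 3 single libraries, and without TAC NRG1 4 and 5 had limma adjusted p of 0.210, 0.197 and 0.136.

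The mouse Nrg1 gene itself was too low to be tested. Its reads per library were 4 to 12 in sham (41 in total), 1 to 8 in TAC saline (19) and 0 to 4 in TAC NRG1 (7).

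The mean distance of TAC NRG1 4 and 5 to the other 3 TAC NRG1 libraries was 28.9% larger than the mean distance among those 3. With every library thinned to the fewest reads the excess was 39.74% of its full-depth value, still the largest of 30 pairs. Thinning adds counting noise to every distance, so this share falls even where depth has no part. The excess in squared distance kept 59.1% ± 3.17 (SD over 20 thinnings). Over the 3712 genes with a mean of at least 100 reads the excess kept 64.68% ± 2.36, but 49.3% without TAC NRG1 1, under the limit of 50% set for each library left out, so depth may account for part of it and the tests cannot tell. With a trend over the longest transcript's length removed from each library, the excess kept 94.53%, which counts against a trend over that length. These 2 libraries nonetheless held mt-Rnr2 at 15650 and 13480 CPM (40470 to 57530 in the other 3). Across genes the difference, 4 and 5 minus 1 to 3, had a Spearman correlation of -0.25 with transcript length. RNA quality was not tested and stays open, and no biological explanation was tested, as the labels give no difference between these libraries.

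Ribosomal protein genes were higher in TAC NRG1 with a median log2 fold change of 0.22. A transcript length trend between libraries could raise that value. With the trend removed the median was 0.1173. That counts against length as the whole cause only so far as the longest transcript's length captures the trend. Without TAC NRG1 4 and 5 the median was 0.1316, which counts against those libraries alone. With both steps the list's mean was 0.0797 ± 0.0137, against 0.2214 ± 0.0672 with all libraries and the trend kept (SE between libraries). No limit was set for both steps together, so the trend and those libraries may jointly account for a large part of the rise. The remaining difference may reflect NRG1, but the list call did not hold with an estimated correlation in the 3 fits where it was tested, all libraries, trend removed and libraries left out (adjusted p of 0.128 to 0.230).

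Apln and Nrp2 fell in TAC NRG1. An even loss of endothelial cells from the tissue could lower both. It would need the endothelial list to fall by at least 0.56 on the log2 scale, the value set as the prediction. The median of its 25 members was -0.1804, which counts against an even loss as the whole cause. Loss of only a subset of these cells need not lower the whole list, so it was not tested and stays open. With the length trend removed the smaller of the 2 falls was -1.0394, which counts against a trend over the longest transcript's length. A change in the expression of Apln and Nrp2 under NRG1 was also left as a possible account and was not tested further.

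The libraries of each comparison were also regrouped into other sets of 5 and 5, and 1 of 100 groupings, the real one, gave as many genes as the real labels. The real counts were 1180, 143 and 1777 for TAC saline against sham saline, TAC NRG1 against TAC saline and TAC NRG1 against sham saline, and the highest among the others were 389, 123 and 1. The 389 and the 123 came from groupings that swapped only 1 library between the groups. For TAC saline against sham saline, the other groupings with 1 library swapped gave 0 to 122 genes. For TAC NRG1 against TAC saline they gave 0 to 3. Closeness to the real labels therefore does not by itself account for the 389 or the 123, and why those groupings stood out was not tested. Apart from the 123, no regrouping for TAC NRG1 against TAC saline gave more than 3 genes. Every other grouping mixed libraries of the 2 real groups, so a real difference widens the spread within it and lowers its count. The regroupings therefore do not show how many of the 143 calls come from uneven libraries such as TAC NRG1 4 and 5.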
